A study of Homo sapiens with 28 samples.

How the data were processed

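MYBBP1A ChIP-seq libraries and matching input libraries came from HS766T wild-type cells, 2 hemizygous HS766T clones, PANC1, ASPC1, BxPC3 and BJ cells, with 2 libraries of each kind per population (28 libraries). Groups were taken from the sample titles. Per the labels' protocols, chromatin was sonicated and the libraries were amplified and size-selected before sequencing. The labels call the replicates biological replicates.

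The deposited files used here were 7 peak lists of 3 columns (chromosome, start, end), with no header and no height, fold enrichment, p-value or score. Per the submitters' processing notes, the tools named were Bowtie2 2.3.4.1, SAMtools 1.1, Picard, bedtools and MACS2 2.1.0, and the genome build was hg19. The notes as held here give these tools no role or order, so aligner settings, duplicate handling and peak thresholds are not given in the sources used here. Each list name states that replicates were pooled, so no per-replicate value could be taken from them, and it names the input. The authors' lists carry a further tag, NoBL, whose meaning is not stated. Read counts per library were not in these lists, so the depth behind a peak was unknown and no detection floor is given. A list called from deeper or cleaner libraries can be longer, with wider peaks, without any difference in binding, so median widths were tested only within a list. Across the 5 unedited lines, 7 summary measures of the lists, among them the number of peaks and the shortest, median and widest width, were only screened for outlying values with Dixon's criterion. Signal tracks were not used here.

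Positions are given 1-based on hg19. Peaks of 2 lists counted as shared where they overlapped by at least 1 base. Each share was set against 1000 circular shifts, with 1 random shift per chromosome per draw (seed 1, one-sided permutation test, smallest p 0.000999), adjusted by Benjamini-Hochberg over 42 ordered pairs. Shares carry exact Clopper-Pearson intervals at the 95% level. Regions across lists were made by merging overlapping peaks. Median widths were compared within a list by a two-sided permutation test with 100000 resamples (smallest p 1e-05), or an exact one where a group had fewer than 10 peaks and enumeration was possible, adjusted over 15 tests. Peaks per chromosome were tested against each chromosome's share of length by a two-sided exact binomial test over 161 tests, on chromosomes 1 to 22 and X. The highest coordinate seen in any list stood for the length, since no genome was used here. The threshold for adjusted p was 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

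The overlap, merging and chromosome tests and the rule for naming regions were set before the data were examined. The named regions were up to 20 called in the wild type and both clones, the 5 strongest wild-type peaks in neither clone, the 5 strongest peaks of each other list, and 20 regions called in the most lists. The design had foreseen fold enrichment as the measure of strength. As the lists gave none, peak width was used for ranking and for the within-list tests. The alternatives foreseen by caller significance were replaced by width in the same way, and these replacements were chosen after seeing the data. Also chosen afterwards were the unplaced contig counts and their binomial tests, the protein-coding gene baseline, the correlations over chromosomes, the comparison at equal length of the 4 longer lists, and the Fisher's tests on clones, regions and chromosomes. Unplaced contigs here include all sequences outside the assembled chromosomes, also gl000205 and gl000195, whose names assign them to chromosomes 17 and 7. Gene numbers per chromosome (19974 protein-coding genes) came from a RefSeq table of GRCh38.p14, from which no coordinate was used.

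An hg19 gene annotation was not used here, so the planned tests of 16 gene lists and of genomic features were not run, and no gene is named at a peak. Widths of single peaks from different lists are printed side by side as values without a test.

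The procedures were tested on simulated data. With 49.8% of 219 peaks copied between lists modelled on HS766T wild type and clone 1, a share of 49.8% was recovered. With 50% of 1476 peaks copied between lists modelled on BJ and ASPC1, 50% was recovered. Copied peaks kept their exact positions, so this recovery checks the counting only. With no shared peaks, 0% of 100 simulated pairs of the first kind and 8% of 100 of the second kind had p under 0.05. These pairs were placed uniformly, without the clustering of real peaks, and were tested with 100 shifts each. In width tests modelled on ASPC1 with no difference, 4% of 50 draws had p under 0.05.

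Alternatives were a reciprocal coverage of 50%, sharing within 1000 bases, random placement on the chromosome, merging at a gap of 1000 bases, the wider part of each list above its median width, lists of equal length, 1 peak per Mb, lists without unplaced contigs, and the gene baseline.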

Results

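MYBBP1A (MYB binding protein 1a), a mainly nucleolar protein known as a transcriptional co-regulator, was mapped on chromatin by ChIP-seq in 5 human cell lines. HS766T, PANC1, ASPC1 and BxPC3 are pancreatic cancer lines and BJ is a fibroblast line. HS766T was profiled as wild type and as 2 CRISPR-modified clones hemizygous for MYBBP1A, that is, clones retaining a single intact copy of the gene. Each of these 7 cell populations had 2 immunoprecipitated libraries and 2 input libraries, 28 libraries in total. The deposited data used here were 7 peak lists, 1 per population, each made from pooled replicates and input according to its name. A list gave the chromosome, start and end of each peak on hg19 and no height, score or read count, so read depth was unknown and no spread between replicates could be had. A region absent from a list was not called there, which does not show that it was unbound. Tests below were made over peaks or positions, not over replicates, and intervals are 95% Clopper-Pearson intervals that cover counting error only. Genes at the peaks were not analysed here.

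The HS766T wild-type list held 219 peaks covering 44896 bases. Clone 1 had 162 peaks over 31128 bases and clone 2 had 87 peaks over 17881 bases. The other lines had longer lists, with 1598 peaks in PANC1, 3407 in ASPC1, 1839 in BxPC3 and 1476 in BJ, which is 6.74 to 15.6 times the HS766T wild-type number. Peaks were narrow in HS766T, with a median width of 158 bp in the wild type, 146 bp in clone 1 and 134 bp in clone 2. Median widths were 292 bp in PANC1, 513 bp in ASPC1, 319 bp in BxPC3 and 328 bp in BJ. These numbers and widths came from single pooled lists, so the differences between populations could not be set against a replicate spread.

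The title of the series asks whether MYBBP1A stays on chromatin when cells are hemizygous for it. Of the 219 wild-type HS766T peaks, 136 were also called in at least 1 clone (62.1%, interval 55.3 to 68.6%) and 83 in neither. Both clones shared 73 of them (33.3%, interval 27.1 to 40.0%), 55 were shared with clone 1 alone and 8 with clone 2 alone. Overlap with clone 1 reached 128 wild-type peaks (58.4%, interval 51.6 to 65.0%) and overlap with clone 2 reached 81 (37.0%, interval 30.6 to 43.8%). When peaks were shifted around their chromosomes, at most 4 of the wild-type peaks met a peak of either clone in any of 1000 draws. Each observed overlap had p = 0.000999 in this one-sided permutation test, the smallest it can give, and the same value after Benjamini-Hochberg adjustment over 42 ordered pairs of lists. The shifts ignore where genes lie, and all 42 ordered pairs reached this p. The test therefore does not separate binding retained in the clones from sites common to many cells.

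Read in the other direction, the clone peaks lay mostly at wild-type regions. Of the 162 clone 1 peaks, 133 overlapped a wild-type peak (82.1%, interval 75.3 to 87.7%), and 84 of the 87 clone 2 peaks did (96.6%, interval 90.3 to 99.3%), both at the smallest permutation p of 0.000999. The remaining 3 clone 2 peaks were at chromosome 8, 56987097 to 56987202, chromosome 12, 107167926 to 107168032, and chromosome 19, 49947055 to 49947158 (hg19). These 3 positions were chosen after their values were seen. Each of the 3 was also called in PANC1, ASPC1, BxPC3 and BJ, as were 28 of the 29 clone 1 peaks absent from the wild type. Between the clones, 78 clone 1 peaks overlapped clone 2 (48.1%, interval 40.2 to 56.1%) and 77 clone 2 peaks overlapped clone 1 (88.5%, interval 79.9 to 94.3%). List length bears on all of these shares. With each pair of lists reduced to its widest peaks at equal number, 64.4% of 87 wild-type peaks overlapped clone 2 (interval 53.4 to 74.4%) and 70.4% of 162 overlapped clone 1 (interval 62.7 to 77.3%). Among the clone shares, those that then fell were clone 2 in the wild type, to 67.8% (interval 56.9 to 77.4%), clone 1 in the wild type, to 73.5% (interval 66.0 to 80.1%), and clone 2 in clone 1, to 70.1% (interval 59.4 to 79.5%). The share of clone 1 in clone 2 instead rose, to 71.3% (interval 60.6 to 80.5%).

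**Figure D1:**
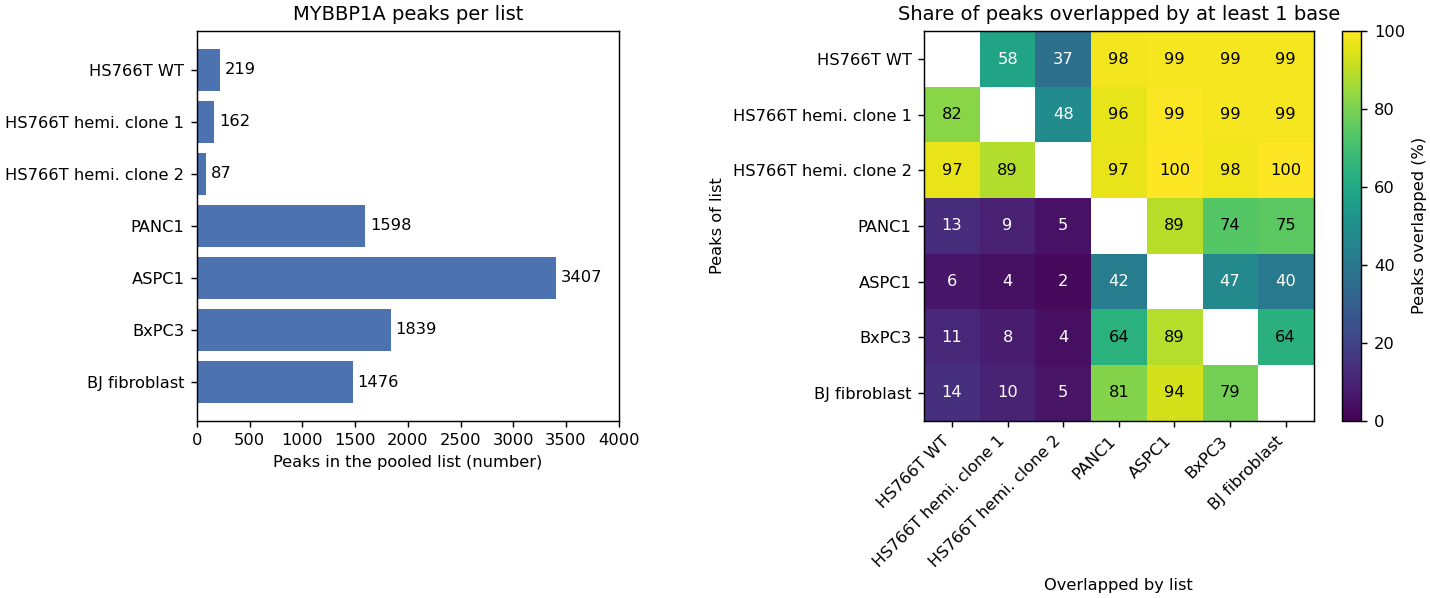
Left, number of MYBBP1A peaks in each of the 7 pooled lists, from 87 in HS766T hemizygous clone 2 to 3407 in ASPC1. Right, percent of the peaks of the list in each row that overlap a peak of the list in each column by at least 1 base, coloured from 0 to 100%, where HS766T rows reach at least 96.3% in the other lines and rows of the other lines at most 13.8% in HS766T lists.

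Many of the same wild-type peaks were called in both clones. A wild-type peak called in clone 1 was also called in clone 2 more often than one absent from clone 1, with an odds ratio of 13.8 (two-sided Fisher's exact test, p = 2.91e-14). Of the 63 wild-type peaks found in 1 clone and not the other, 55 were in clone 1 and 8 in clone 2, and the clone 1 list was also the longer. With clone 1 reduced to its 87 widest peaks, the length of the clone 2 list, 19 wild-type peaks were in clone 1 alone and 22 in clone 2 alone. Both the Fisher's test and this count were chosen after seeing the data. The Fisher's test did not account for peak width, and wild-type peaks in both clones were wider (median 210 bp) than those in neither (133 bp). Lists that share only their strongest peaks could give such an odds ratio too.

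Wild-type peaks that were also called in a clone were wider. Their median width was 185.5 bp (n = 136), against 133 bp for the 83 called in neither (two-sided permutation test over peaks, adjusted p = 1.88e-05 over 15 width tests). By class, the median was 210 bp for the 73 peaks in both clones, 161 bp for the 55 in clone 1 alone and 155 bp for the 8 in clone 2 alone. Within clone 1, the 133 peaks shared with the wild type had a median of 158 bp and the 29 absent from it 117 bp (permutation test, adjusted p = 0.0109). Within clone 2 the medians were 141 bp for 84 shared peaks and 106 bp for the other 3, a difference that an exact permutation test did not separate from chance (p = 0.34). Width stood in for peak strength because the lists gave no height.

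**Figure D2:**
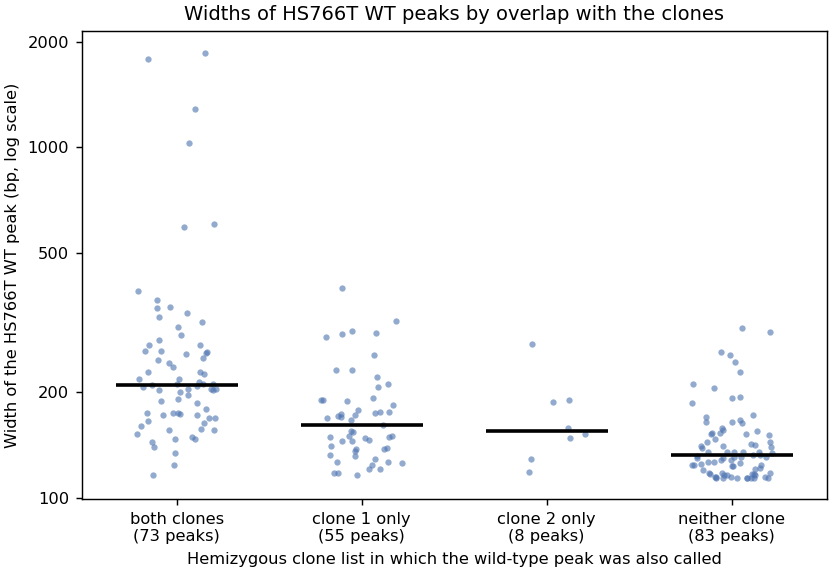
Width in bp, on a log axis, of each of the 219 HS766T wild-type peaks (points), grouped by whether a peak of hemizygous clone 1 or 2 overlapped it, with the median of each group as a black line. The medians are 210 bp for both clones, 161 bp for clone 1 only, 155 bp for clone 2 only and 133 bp for neither.

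The same regions held wide peaks in the other lines. Within each of the other 4 lists, peaks at HS766T wild-type peaks were wider than the rest, with medians of 444 against 275 bp in PANC1, 790 against 494 bp in ASPC1, 493 against 304 bp in BxPC3 and 470 against 313 bp in BJ (n = 203 at wild-type peaks in each list; permutation tests, adjusted p = 1.88e-05 in each). Peaks at wild-type regions kept in a clone were in turn wider than peaks at wild-type regions called in neither clone. By permutation tests, those medians were 484 against 402.5 bp in PANC1 (adjusted p = 0.00036), 829 against 694.5 bp in ASPC1 (adjusted p = 0.00085), 549.5 against 428 bp in BxPC3 (adjusted p = 0.000409) and 520.5 against 407 bp in BJ (adjusted p = 5e-05). Requiring 50% reciprocal coverage left between 2 and 14 peaks in the smaller group, ended these last 4 calls and turned the direction in ASPC1 and BJ. It also ended the call in ASPC1 for peaks in against absent from the wild-type list, where 5 peaks remained.

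The widest wild-type peaks kept in both clones lay first on hg19 contigs, unplaced (gl000220) or assigned to chromosome 17 (gl000205) or 7 (gl000195). They were on contig gl000205 at 85090 to 86952 (1863 bp in the wild type, 1552 bp covered in clone 1 and 1473 bp in clone 2), on contig gl000220 at 117680 to 119465 (1786, 1876 and 1942 bp), on contig gl000195 at 31729 to 33013 (1285, 1201 and 994 bp) and at 30560 to 31588 (1029, 978 and 1018 bp), again on gl000220 at 7288 to 7891 (604, 562 and 510 bp) and on gl000205 at 87233 to 87825 (593, 527 and 463 bp). Peaks on these same contigs were also among the widest in ASPC1, BxPC3 and BJ. Whether reads from repeated sequence pile up on these contigs was not tested, so peak width there may not reflect binding. On assembled chromosomes the widest kept peaks were at chromosome 1, 156736926 to 156737314, with 389 bp in the wild type, 305 bp in clone 1 and 345 bp in clone 2. Next came chromosome 19, 4791405 to 4791772 (368, 265 and 353 bp), chromosome 1, 54304049 to 54304398 (350, 256 and 206 bp), chromosome 12, 6961507 to 6961854 (348, 369 and 273 bp) and chromosome 16, 30933753 to 30934089 (337, 368 and 259 bp). The other 9 of the 20 widest kept peaks measured 262 to 329 bp in the wild type.

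The 5 widest wild-type peaks called in neither clone were at chromosome 22, 19466904 to 19467209 (306 bp), chromosome 11, 2421681 to 2421978 (298 bp), chromosome 3, 14692998 to 14693257 (260 bp), chromosome 5, 171433696 to 171433951 (256 bp), and chromosome 9, 102861265 to 102861508 (244 bp). All 5 regions were called in PANC1, ASPC1, BxPC3 and BJ. The peaks there measured 499 to 760 bp in PANC1 and 781 to 1202 bp in ASPC1.

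The lists of the other lines show which called regions are common to different cells. Input libraries were the only controls, so regions enriched without MYBBP1A could not be recognised among them. Every one of the 219 wild-type, 162 clone 1 and 87 clone 2 peaks overlapped a peak of at least 1 other line, and 210 (95.9%), 154 (95.1%) and 82 (94.3%) overlapped peaks in all 4. The wild-type peaks were also contained whole within a peak of at least 1 other line in 219 of 219 cases (lower bound of the interval 98.3%). Because HS766T peaks were narrow, 50% reciprocal coverage was met by only 17.4% of wild-type peaks in PANC1, 2.28% in ASPC1, 16.9% in BxPC3 and 12.8% in BJ. With lists reduced to their widest peaks at equal number, 49.8% of wild-type peaks overlapped PANC1, 26.9% ASPC1, 40.6% BxPC3 and 46.1% BJ. For the clones these equal-length shares were 21.8 to 47.5%.

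Merging the 7 lists gave 3778 regions. Of these, 1740 were in a single list, 68 in all 7 lists and 997 in all 4 of PANC1, ASPC1, BxPC3 and BJ. HS766T wild type had a peak at 199 of the 997 regions common to the 4 lines (19.96%, interval 17.5 to 22.6%), against 6 of the 2781 regions in 1 to 3 of them (0.216%, interval 0.0792 to 0.469%; two-sided Fisher's exact test chosen after seeing the data, p = 1.91e-112). ASPC1 alone held 1435 regions, PANC1 110, BxPC3 152 and BJ 43. These single-list regions are all among the 2781, and more of them came from ASPC1, the longest list, than from the others. Peaks in no other list were also narrower, with a median of 372 bp against 626 bp for the other ASPC1 peaks. The contrast above was not adjusted for list length or peak width, so it partly sets wide peaks against narrow ones. Of the regions in each list, 57.8% in ASPC1 were also in another of the 4 lines, compared with 93.1% in PANC1, 91.5% in BxPC3 and 97.1% in BJ. List length limits these shares, since the 3401 ASPC1 regions outnumber those of any shorter list that could hold them.

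Pairwise, ASPC1 took in 89.4% of PANC1 peaks (interval 87.7 to 90.8%), 88.7% of BxPC3 peaks (interval 87.2 to 90.2%) and 93.7% of BJ peaks (interval 92.3 to 94.9%). Between 40.3 and 47.1% of ASPC1 peaks were found in each of these 3 lists. At 50% reciprocal coverage, ASPC1 took in 40.2% of PANC1, 51.0% of BxPC3 and 51.5% of BJ peaks, and 18.9 to 27.5% of ASPC1 peaks were found in the 3 lists. Of the fibroblast peaks, 81.3% (interval 79.2 to 83.3%) were in PANC1 and 79.3% (interval 77.1 to 81.3%) in BxPC3. Each of the 42 ordered pairs of lists exceeded all 1000 shifts (permutation p = 0.000999), but at 50% reciprocal coverage 4 pairs, clone 1 and clone 2 with ASPC1 in both directions, no longer passed (adjusted permutation p = 0.118 to 0.141). At equal length, with the 1476 widest peaks of each list, PANC1 and BJ shared 78.1% (interval 75.9 to 80.2%), BxPC3 and BJ 71.5% (interval 69.2 to 73.8%) and ASPC1 and BJ 67.8% (interval 65.3 to 70.1%). The 3 pairs of cancer lines shared 65.0 to 67.9%. The 1476 peaks were the whole BJ list. Pairs with BJ thus cut only the other list by width, while pairs of cancer lines cut both, which limits this comparison. The equal-length comparison was chosen after seeing the data.

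Among the regions called in all 7 lists, the order was set by the sum, over the 7 lists, of the width rank of the widest peak in the region. On assembled chromosomes the first was chromosome 16, 30933490 to 30934922, where peaks covered 551 bp in the HS766T wild type, 1181 bp in PANC1, 1422 bp in ASPC1, 1359 bp in BxPC3 and 1227 bp in BJ. Next were chromosome 1, 156736678 to 156737831 (389 bp in the wild type and 1154 bp in ASPC1), chromosome 19, 42746468 to 42747762 (506 and 1295 bp), chromosome 17, 27278618 to 27279688 (237 and 1071 bp), and chromosome 11, 82996608 to 82997733 (350 and 1126 bp). Of the 20 highest such regions, 9 held one of the 20 widest wild-type peaks kept in both clones. Part of this agreement is built in. The 68 regions in the wild type and both clones were also the 68 in all 7 lists, and wild-type widths entered both orders. A wide peak at chromosome 19, 50379743 to 50381037 in BJ (1295 bp) was called in PANC1, ASPC1 and BxPC3 and in no HS766T list. Further wide ASPC1 peaks were at chromosome 11, 64037105 to 64039168 (2064 bp), and chromosome 8, 145158371 to 145160200 (1830 bp), both called in the wild type and clone 1 and not in clone 2.

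Contig gl000220, an unplaced sequence of hg19 that carries a copy of the ribosomal DNA repeat, held peaks in all 7 lists. A part of the repeat is the template of the nucleolar ribosomal RNA precursor, and where that part lies on the contig was not analysed here. HS766T wild type, clone 1 and clone 2 each had 3 peaks there, covering 2524, 2784 and 2564 bases. Covered bases were 18134 in 16 PANC1 peaks, 15819 in 21 ASPC1 peaks, 7303 in 11 BxPC3 peaks and 3570 in 4 BJ peaks. The number of peaks exceeded the contig's share of sequence in every list (two-sided exact binomial tests, adjusted p from 3.97e-35 in ASPC1 to 4.53e-06 in BJ over 77 contig tests). Regions at 6829 to 8250 and 117459 to 120381 were called in all 7 lists. From 120505 to 145674, PANC1 had 13 peaks over 14474 bases, ASPC1 17 peaks over 11349 bases, BxPC3 9 peaks over 4212 bases and BJ 1 peak of 225 bases, while none of the 3 HS766T lists had a peak. The contig was examined after seeing the data, and reads from the many genomic copies of the repeat can pile up on it.

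**Figure D3:**
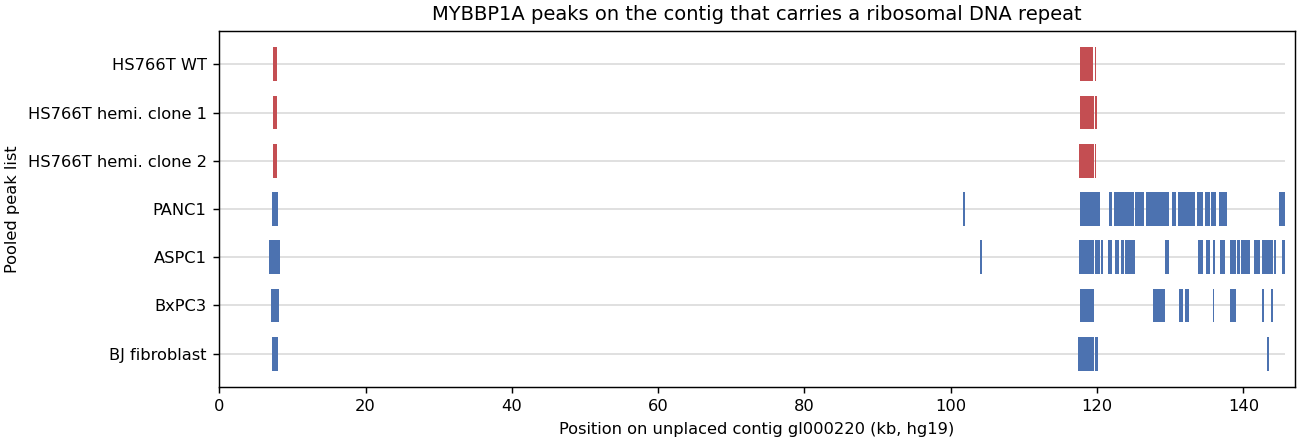
Positions of peaks (bars) along hg19 contig gl000220 in kb for the 7 pooled lists, with HS766T lists in red and the other lines in blue. All lists have peaks near 7 kb and 118 kb, and 13 PANC1, 17 ASPC1, 9 BxPC3 and 1 BJ peaks lie beyond 120505.

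Across chromosomes, peaks were concentrated on chromosomes 16, 19 and 20, which exceeded their share of sequence length in each of the 7 lists (two-sided exact binomial tests over peaks, Benjamini-Hochberg adjustment over 161 tests). Chromosome 19, known for its high gene density and its clusters of zinc finger genes, made up 1.95% of the length. By these exact tests it held 13.8% of HS766T wild-type peaks (interval 9.45 to 19.2%, adjusted p = 3.84e-15), 15.4% in clone 1 (interval 10.0 to 22.3%, adjusted p = 2.84e-13) and 10.5% in clone 2 (interval 4.66 to 19.7%, adjusted p = 0.000449). Shares in the other lines were 15.0% in PANC1 (interval 13.3 to 16.9%), 9.21% in ASPC1 (interval 8.26 to 10.2%), 14.9% in BxPC3 (interval 13.3 to 16.6%) and 17.6% in BJ (interval 15.6 to 19.6%). Chromosome 4 fell below its length share in 6 lists and chromosome X in 5. With 1 peak kept per Mb, a setting that caps short chromosomes with many peaks, chromosome 19 stayed above its length share in all 7 lists, at 3.48% in ASPC1 to 12.1% in clone 1. Chromosome 16 then passed only in the 3 HS766T lists and chromosome 20 in all but ASPC1, while chromosome 4 was below in 6 lists and X in 4. With the wider peaks of each list, none of the 3 chromosomes passed in clone 2, where chromosome 19 held 2 peaks (ratio 2.92, adjusted p = 0.27 by the exact test), and chromosome 20 did not pass in clone 1.

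Peak density followed gene density. Peaks per Mb rose with protein-coding genes per Mb over 23 chromosomes, with Spearman's rho of 0.55 in the HS766T wild type (permutation p = 0.00706; Pearson's r = 0.89, permutation p = 0.00018). It was 0.63 in clone 1 (p = 0.00145; r = 0.88, p = 0.00031) and 0.65 in clone 2 (p = 0.00095; r = 0.81, p = 0.00015) by the same permutation test. In the other lines it was 0.86 in PANC1 (p = 2e-05; r = 0.95, p = 1e-05), 0.78 in ASPC1 (p = 1e-05; r = 0.95, p = 1e-05), 0.84 in BxPC3 (p = 1e-05; r = 0.93, p = 1e-05) and 0.82 in BJ (p = 1e-05; r = 0.93, p = 1e-05). This was 1 of 4 relations computed per list, and its adjusted p over the 7 lists was at most 0.00706. Without the 2 chromosomes farthest from the median gene density, r was 0.61 in the wild type, 0.64 in clone 1, 0.66 in clone 2, 0.86 in PANC1, 0.85 in ASPC1, 0.84 in BxPC3 and 0.88 in BJ. Chromosomes are neither samples nor independent replicates, and gene numbers came from GRCh38.p14, another build than the peaks. Against its 7.26% share of protein-coding genes, in the same exact binomial test, chromosome 19 held 1.90 times its share of wild-type peaks (adjusted p = 0.00556), 2.12 times in clone 1 (adjusted p = 0.00485), 2.07 times in PANC1 (adjusted p = 1.14e-23), 1.27 times in ASPC1 (adjusted p = 0.000266), 2.05 times in BxPC3 (adjusted p = 8.94e-27) and 2.42 times in BJ (adjusted p = 1.1e-36). In clone 2 the ratio was 1.45 and did not pass the exact test (adjusted p = 0.525). Chromosome 16 exceeded its gene share in 6 of the 7 lists, without clone 2, and chromosome 20 in 4, without clone 2, PANC1 and BJ. Chromosomes 4 and X were each below their gene share in 4 lists, those of PANC1, ASPC1, BxPC3 and BJ. The gene baseline and the correlations were chosen after seeing the data.

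**Figure D4:**
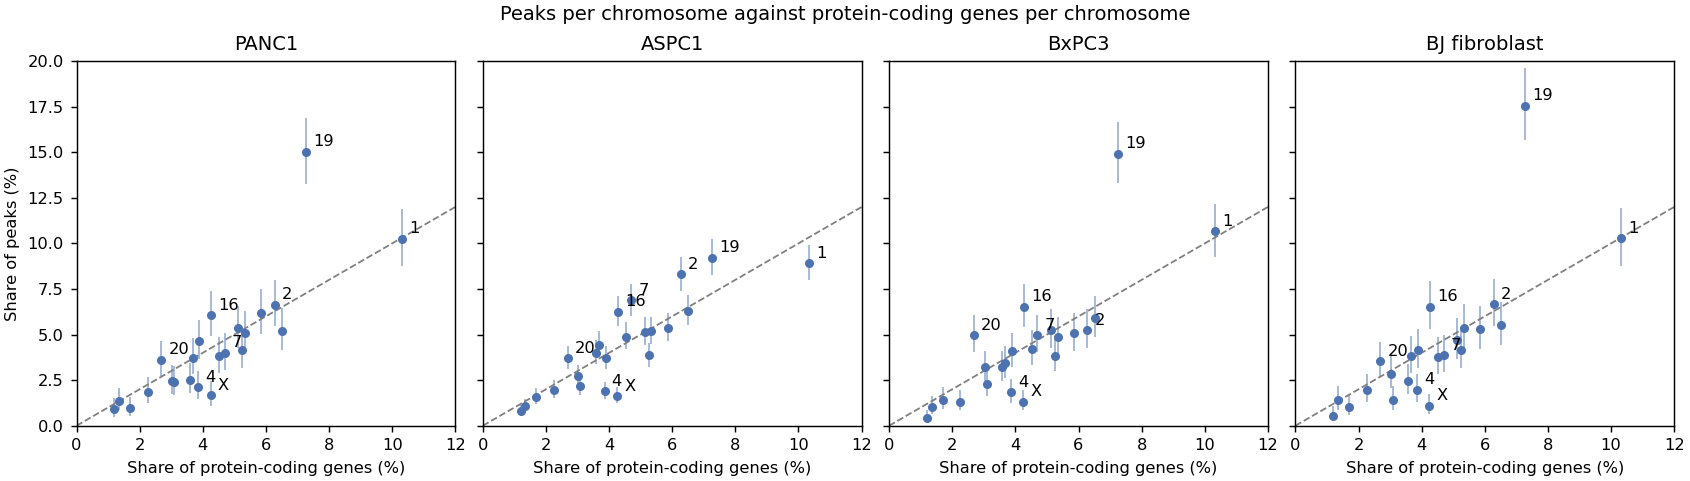
Percent of peaks on each of 23 chromosomes (points, with 95% Clopper-Pearson intervals as bars) against the percent of protein-coding genes on that chromosome, for PANC1, ASPC1, BxPC3 and BJ, with equality as a dashed line and 8 chromosomes labelled. Chromosome 19, with 7.26% of the genes, holds 15.0, 9.21, 14.9 and 17.6% of the peaks.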

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

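The tests in this part were chosen after the results were seen, except 2 added tests whose outcome had not been seen, the comparison of peak widths in the other lines at kept and lost HS766T wild-type regions and the zinc finger gene correlation. Among the 5 unedited lines, HS766T stood apart at the low end in its shortest peak, 114 bp, and in its widest peak, 1863 bp. In the other 4 lines the shortest peaks measured 178 to 188 bp and the widest 3184 to 3566 bp. The gap divided by the range was 0.865 for the shortest and 0.776 for the widest, above Dixon's critical value of 0.71 for 5 values. Both ends of 7 measures were examined (14 in all), and chance flags about 1 in 20 groups.

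The first pattern weighed is that the clones had shorter lists than the wild type. Loss of sites regardless of their strength would leave peaks of equal width in the other lines at kept and lost regions, but kept regions held wider peaks in 4 of the 4 other lists, each with a permutation p under 0.05, which argues against it as the whole cause. At 50% reciprocal coverage the difference was 97 bp in PANC1 and 82.5 bp in BxPC3 but reversed to -1390 bp in ASPC1 and -29 bp in BJ, none past the threshold, with 2 to 14 peaks in the smaller group. For a lower sensitivity of peak calling in the clones, clone 1 peaks absent from the wild type were 41 bp narrower at the median than shared ones, but unshared peaks were narrower in each of the 4 other lists too, so this decides nothing. Uniformly lower occupancy in the hemizygous clones, the biological explanation the design gives, needs peak heights, and with 0 columns of height, score or depth in the lists it cannot be told apart from lower sensitivity.

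The second pattern is that HS766T lists were shorter than those of the other lines. A different library preparation or peak calling for HS766T would show in peak widths, and the shortest peak of any other list was at least 64 bp longer than that of any HS766T list. That gap could also come with the cell line itself. The line and any difference in preparation are confounded here and cannot be told apart.

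The third pattern is the excess of peaks on chromosome 19. In 4 of the 4 longer lists the chromosome exceeded its share of protein-coding genes (ratios of 1.27 in ASPC1 to 2.42 in BJ). This argues against gene number as the whole cause but does not exclude it, since the test counts neighbouring peaks as independent. With 1 peak per Mb, chromosome 19 held 3.48% of peaks in ASPC1 to 5.84% in BJ, below its 7.26% of genes. That setting caps short chromosomes and was not tested against the gene share. Zinc finger genes concentrated on chromosome 19 are a candidate explanation. Without that chromosome, peaks per protein-coding gene rose with the share of zinc finger genes at an unadjusted p under 0.05 in 2 of the 4 longer lists, with Spearman's rho of 0.48 in ASPC1 (permutation p = 0.027), 0.44 in BxPC3 (p = 0.041), 0.39 in PANC1 (p = 0.0759) and 0.37 in BJ (p = 0.092). Every one of these had an adjusted p of 0.129 over 7 lists, so this stays open, and other features of the chromosome were not tested.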

How the results depend on the processing

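No paired analysis was possible because each list was called on pooled replicates. Leaving out each replicate could not be done for the same reason. Alternatives by caller significance, gene list and genomic feature were not run, and those by width, by Mb, without unplaced contigs or by gene baseline were chosen after seeing the data. The 6 overlaps among HS766T lists stayed past the threshold in all 7 alternatives, from 30.6 to 97.7%, as did 290 of 294 overlap alternatives over all pairs. Widths kept their direction and side of the threshold in 15 of 15 tests without unplaced contigs. Read depth was unknown, so what it limits could not be measured.

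At 50% reciprocal coverage, overlaps with ASPC1 no longer passed for clone 1 (0.617% of its peaks), clone 2 (1.15%) and the reverse directions (0.0294% of ASPC1 peaks for each clone). The width difference in ASPC1 between peaks in and absent from the wild-type list was 59 bp and no longer passed. Between kept and lost regions it was 97 bp in PANC1 and 82.5 bp in BxPC3, no longer past the threshold, and reversed to -1390 bp in ASPC1 (3 against 2 peaks) and -29 bp in BJ (20 against 8). This setting removes most pairs by construction, since HS766T peaks are far narrower than those of the other lines.

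With the wider part of each list, which holds fewer peaks by construction, regions numbered 32 in all 7 lists, 32 in the wild type and both clones, 457 in all 4 other lines, 121 in any HS766T list and 722 in ASPC1 alone. Chromosomes below their length share numbered 2 in the wild type, 0 in clone 1 and 5 in BJ, and the chromosome 19 ratio in clone 2 was 2.92 and no longer passed.

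With 1 peak per Mb, 2 chromosomes were below their share in the wild type. Above and below numbered 3 and 3 in PANC1, 2 and 2 in ASPC1, 3 and 2 in BxPC3, and 3 and 3 in BJ. Against the protein-coding gene share, chromosomes below numbered 2 in the wild type, 0 in clone 1, 2 in PANC1, 5 in ASPC1, 5 in BxPC3 and 3 in BJ. Those above numbered 0 in clone 2, 2 in PANC1, 3 in BxPC3 and 2 in BJ, and the chromosome 19 ratio in clone 2 was 1.45 and no longer passed. Against length, 5 to 6 chromosomes had been above and 9 to 12 below in the 4 longer lists, and 4, 1 and 0 below in the wild type, clone 1 and clone 2. For these chromosome counts the cause was not tested.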

Other observations

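All tests in this part were chosen after the data were seen, and no explanation was tested for the values given. The 1426 regions on assembled chromosomes called in ASPC1 alone were spread differently from the 992 called in all 4 of PANC1, ASPC1, BxPC3 and BJ. Chromosome 19 held 4.14% of the ASPC1 regions (interval 3.16 to 5.30%) and 16.7% of the common ones (interval 14.5 to 19.2%; two-sided Fisher's exact test, adjusted p = 1.99e-23 over 92 tests). By the same exact test, chromosome 7 held 9.47% of them against 3.53% (adjusted p = 1.9e-07), chromosome 2 held 10.7% against 6.25% (adjusted p = 0.0034) and chromosome 1 held 7.57% against 11.5% (adjusted p = 0.0213). Of the 43 regions called in BJ fibroblasts alone, 26 lay on chromosome 19 (60.5%, interval 44.4 to 75.0%, Fisher's exact test, adjusted p = 2.24e-08). Chromosome X held 6 of the 87 regions on assembled chromosomes called in PANC1 alone (6.90%), against 1.11% of the common regions (Fisher's exact test, adjusted p = 0.0213). These Fisher's tests and intervals count neighbouring regions as independent, though peaks cluster along chromosomes, so the p-values can be too small. They were not repeated with 1 region per Mb. Copy number in these lines was not analysed here.

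Peaks found in a single list were narrower than the other peaks of that list. Median widths of peaks in no other list and in any other were 216 and 299 bp in PANC1, 372 and 626 bp in ASPC1, 225 and 335 bp in BxPC3 (permutation tests, adjusted p = 1.88e-05 in each), and 260 and 331 bp in BJ (adjusted p = 0.00325).

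Contigs outside the assembled chromosomes took 4.11% of HS766T wild-type peaks, 8.02% in clone 1 and 12.6% in clone 2, and 17.4, 23.7 and 37.1% of the covered bases. These were 9 of 219, 13 of 162 and 11 of 87 peaks, so the rising share went with shorter lists. In PANC1 and ASPC1 the contigs took 5.45 and 1.39% of the covered bases. Besides gl000220, contigs gl000205 (assigned to chromosome 17), gl000195 (assigned to chromosome 7) and gl000219 (unplaced) had peaks in all 7 lists. On gl000205 the peaks covered 2677 bases in the wild type, 678 in PANC1, 3417 in ASPC1, 3756 in BxPC3 and 3282 in BJ. PANC1 had 7 peaks on gl000226 and 9 on gl000216, where HS766T and BJ had none.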
